A study of Homo sapiens with 6 samples.

How the data were processed

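RNA was measured in PC-3 cells, an established human prostate cancer line derived from a bone metastasis. Per the labels' protocols, the cells received a lentivirus that overexpresses BHLHE22, a basic helix-loop-helix (bHLH) transcription factor, or a blank-vector lentivirus. There were 3 libraries per group. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with an NEBNext Ultra RNA kit. The sources used here do not say whether the kit or the counting kept strand, or whether the 3 libraries of a group came from separate cultures. The p-values below therefore measure the spread between these libraries, which may be technical.

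The analysis used whole-number read counts per gene, deposited by the authors in 1 table of 58302 Ensembl genes. The same deposited table gives FPKM values. Each FPKM followed from the deposited count, a fixed gene length and the library's summed count: the implied length was the same in every library, within 0.1%, for 100% of 26866 genes with counts in at least 2 libraries. The FPKM columns were used only for that check and for BHLHE22. The submitters' processing notes name CASAVA 1.8, HISAT2 2.1.0, StringTie 1.3.4b and edgeR without a version, with the builds GRCh38 and hg38. The role of each tool and the counting options are not given in the sources used here. Gene positions are those of the deposited table. For 97.6% of the 58039 genes shared with GENCODE release 29 (GRCh38), the position was identical. Columns headed as control were taken as the vector libraries, with the number in each header as the replicate number.

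Counts summed to between 12186723 and 15949537 per library. A gene was tested when edgeR's filterByExpr kept it, which left 15945 genes. These held 99.8% of the counts of each library. Library sizes were scaled by trimmed mean of M-values (TMM). Values per library are counts divided by the scaled library size, in the unit CPM, given as mean ± SD with n = 3 per group. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust dispersions) with the group as the only term, 2-sided. P-values were adjusted by Benjamini-Hochberg over the tested genes, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. A positive log2 fold change means more RNA in the BHLHE22 libraries. The common biological coefficient of variation was 17.0%.

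Before the data were examined, 23 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Their p-values were adjusted by Benjamini-Hochberg over the 23 lists. The same test with the correlation estimated from the data, cameraPR and fry were alternatives. The named genes are BHLHE22, CSF2, PRMT5 and PRDM8. To these come the 12 largest rises and the 12 largest falls among called genes with an approved symbol, a mean of at least 1 CPM and no overlap between groups. Each list adds up to 4 called members with the smallest p, except that all called members of the myeloid recruitment list are given. Genes named outside this rule are said to be so. Some genes and 1 of the lists are not reported here; the adjustment still covers all 23 lists. Fold changes against a group with no counts use a floor of 3 counts over the group. For a group with 1 to 3 counts, the ratio of counts is given with its exact 95% interval. Floors and intervals cover counting error only.

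Other choices were tried for the counts of genes, the genes named by the rule and the gene lists. These were the replicate number as a block, DESeq2's size factors or unscaled library sizes in edgeR, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, and leaving out each library. For the counts of genes they also included a threshold of 0.01 and a test against a 1.2-fold change. After the data were seen, an offset per library for GC content and transcript length, and a fit without mitochondrial genes, were added. GC content and length were known for 99.7% of the tested genes.

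The procedure was tested on simulated data: 5 draws of counts for the 15945 genes, with the real library sizes and dispersions. In each, 100 genes changed 1.5-fold, 100 changed 3-fold and a list of 40 genes shifted. edgeR called 17.2% of the 1.5-fold and 86.2% of the 3-fold genes, 98.9% of the changed genes had the right sign, and 10.5% of the calls were false, above the nominal 5%. The share of false calls was 7.38% for limma-voom and 22.5% for DESeq2. camera found the shifted list in 5 of 5 draws and an unshifted list in 0 of 5. The simulated data held far fewer changed genes than the real comparison. The simulated genes were also drawn independently of each other, so these draws do not test the preset inter-gene correlation.

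Some genes cannot be read with confidence from these counts. Of the 148 protein-coding genes on chromosome 6 between HLA-F and TAPBP, the region of the major histocompatibility complex (MHC), 73 (49.3%) were listed at 0 in every library, against 12.0% on the other chromosomes. They include TAP1, PSMB8 and TNF. RPS9, a ribosomal protein gene elsewhere in the genome, had 0 to 17 counts per library. Values of genes in this region, HLA-B and HLA-C among them, may therefore understate their RNA. Of the 114 named genes, 18 overlap a gene model that holds more than 10% as many counts, such as CMPK2 over RSAD2 and ZBTB21 opposite ZNF295-AS1. CCNE2, GINS2, WDR77, TUBB2B, SREBF1, KRT7, PSME2, CXCL16, SLC16A3, SLC15A3, S100A4, SMURF2, CYP3A7 and MT-ND4L are also among the 18. Without a stated use of strand, reads of pairs on opposite strands cannot be told apart. Other pairs, such as HLA-B and HLA-C, lie on the same strand, where knowing the strand would not separate them.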

Results

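The transcriptomes of 3 vector and 3 BHLHE22 libraries of PC-3 cells were compared. Total counts were 13889050, 15949537 and 14596932 in vector replicates 1 to 3, and 12186723, 13345567 and 15808990 in the BHLHE22 replicates. All 6 libraries differed from each other by more than sampling noise: the chi-square per degree of freedom over genes was 12.1 to 25.3 within groups and 77.3 to 154 between them. The first principal component, with 69.9% of the variance, separated the groups. By its title, the series concerns BHLHE22-dependent infiltration of myeloid-derived suppressor cells in prostate cancer bone metastases. The comparison asks which genes differ when PC-3 cells overexpress BHLHE22.

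BHLHE22 itself was almost undetected in the vector cells and present in every BHLHE22 library. The vector libraries held 1 read each, and the BHLHE22 libraries held 98, 92 and 133. This is a count ratio of 104 after scaling, with a 95% interval of 35.4 to 509. Its level in the BHLHE22 libraries was 7.41 ± 0.72 CPM (SD, n = 3), or 2.39 ± 0.24 in the authors' deposited FPKM. The difference passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 1.01e-05). The gene (ENSG00000180828) lies on chromosome 8 from 64580367 to 64583628 on GRCh38 and consists of 1 exon, with the coding part from 64580791 to 64581933. Reads of a transgene without untranslated regions would fall on the coding part only.

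**Figure D1:**
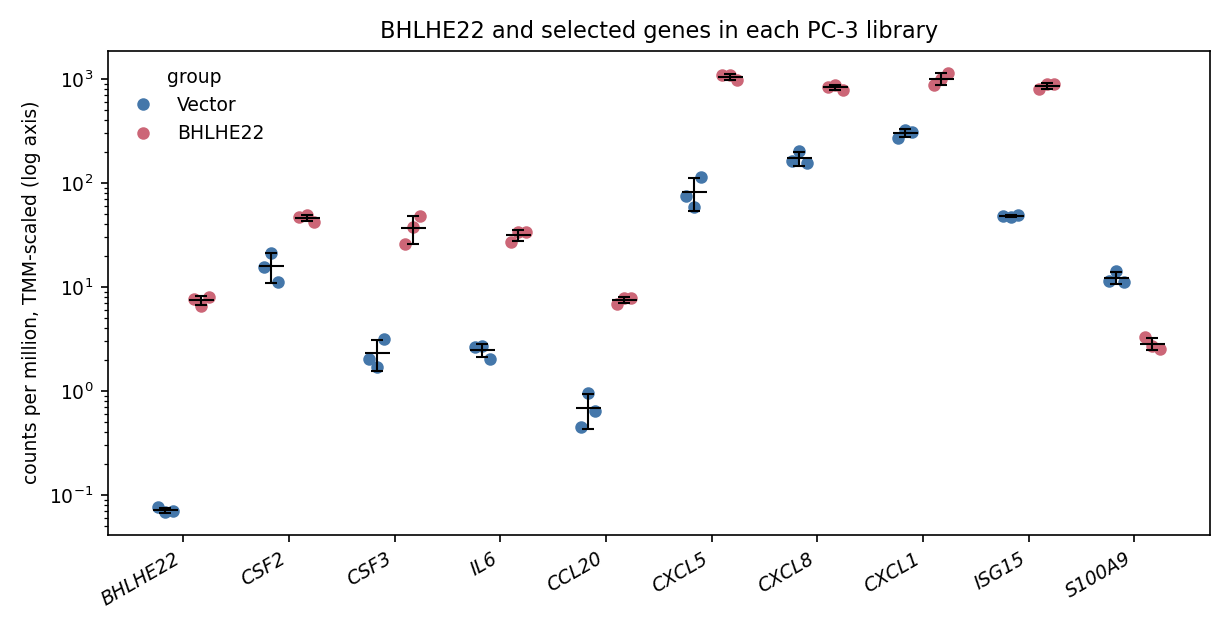
Scaled counts (CPM) on a log axis for 10 genes in each of the 6 libraries; points are libraries, horizontal marks are group means and bars are the SD (n = 3). BHLHE22 rose from 0.071 to 7.41 CPM and CSF2 from 15.9 to 46.0 CPM, with no overlap between groups, while S100A9 fell from 12.2 to 2.84 CPM.

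The difference between the groups was broad. Of 15945 tested genes, 7876 (49.4%) were called, 3996 higher and 3880 lower in BHLHE22 cells. A change of at least 2-fold was found for 2602 genes, of which 1302 were higher and 1300 lower. At least 4-fold changes numbered 509 and at least 8-fold changes 153, with 84 of the latter lower. The groups did not overlap for 9652 genes (60.5%), where chance gives 10%. With unscaled library sizes, 5128 genes were higher and 2890 lower, a higher share of 64.0% against 50.7% with TMM. That scaling shifts the median of all genes by 0.15 on the log2 scale, so the changes below are relative to the typical gene. An adjusted p under 0.01 left 4962 of the calls.

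Of the 12 largest rises, 6 were members of the interferon response list: BST2, XAF1, IFI6, OASL, RSAD2 and EPSTI1. BST2, which encodes the antiviral membrane protein tetherin, rose from 1.15 ± 0.19 to 209 ± 20 CPM (log2 fold change 7.51, SE 0.15, adjusted p = 5.95e-07, edgeR quasi-likelihood). PDCD1LG2, the gene of the checkpoint ligand PD-L2, had 0 counts in vector cells and 165 in BHLHE22 cells, at least 53.4-fold higher. The chemokine gene CXCL11 had 0 against 144 counts, at least 46.6-fold higher. XAF1 had 2 against 278 counts, a ratio of 135 with a 95% interval of 37.0 to 1119. Log2 fold changes were 5.72 for IFI6, 5.19 for OASL, 5.03 for MAP7D3, 4.94 for RSAD2, 4.83 for GBP5, 4.66 for SLC15A3 and 4.52 for EPSTI1; BHLHE22 completes the 12. Leaving out vector replicate 1 gave 6.29 for MAP7D3, and leaving out vector replicate 2 gave 5.41 for SLC15A3 and moved the fitted fold of XAF1 6.37 times. SLC15A3 had 228 counts in all and overlaps TMEM132A, which had 7325 and was named after its values were seen.

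Among the 12 largest falls, the aldo-keto reductase genes AKR1B10 and AKR1B1, neighbours on chromosome 7, fell from 57.8 ± 7.9 to 1.18 ± 0.43 CPM and from 66.7 ± 29.7 to 1.89 ± 0.26 CPM (log2 fold changes -5.61 and -5.13; adjusted p = 1.14e-05 and 0.000264, edgeR quasi-likelihood). MYOC had 214 counts in vector cells and 0 in BHLHE22 cells, at least 73.5-fold lower. ELF5, which encodes an epithelial transcription factor, had 227 against 2 counts, a ratio of 117 with a 95% interval of 32.0 to 972. CCDC83 had 231 against 3 counts, a ratio of 79.4 with an interval of 26.8 to 388. The cytochrome P450 genes CYP3A5 and CYP3A7 had log2 fold changes of -6.07 and -4.20. The kinase gene GRK3 followed with -5.04, TFEC with -4.83, ZNF295-AS1 with -4.51, the adhesion gene CADM2 with -4.37 and PTGS1, the gene of cyclooxygenase-1, with -4.22. Several of these sizes depended on single libraries. The adjusted p of CYP3A7 was 0.0526 without BHLHE22 replicate 1, 0.0681 without replicate 2 and 0.0820 without the low-count filter, and that of MYOC was 0.0805 without the low-count filter. Without vector replicate 2, which had the highest levels, the log2 fold change was -3.04 for CYP3A7 and -4.23 for TFEC, and the fitted fold moved 1.64 times for MYOC and 1.59 times for ELF5. Leaving out BHLHE22 replicates gave -4.96 for PTGS1 (replicate 1), -7.39 for CYP3A5 (replicate 2), and -5.40 for CYP3A5 and -5.41 for CYP3A7 (replicate 3). The fitted log2 fold change of ELF5 was -9.19 without BHLHE22 replicate 3, against -6.61 with it, and the fitted fold of CCDC83 moved 9.09 and 1.56 times without replicates 1 and 3.

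**Figure D2:**
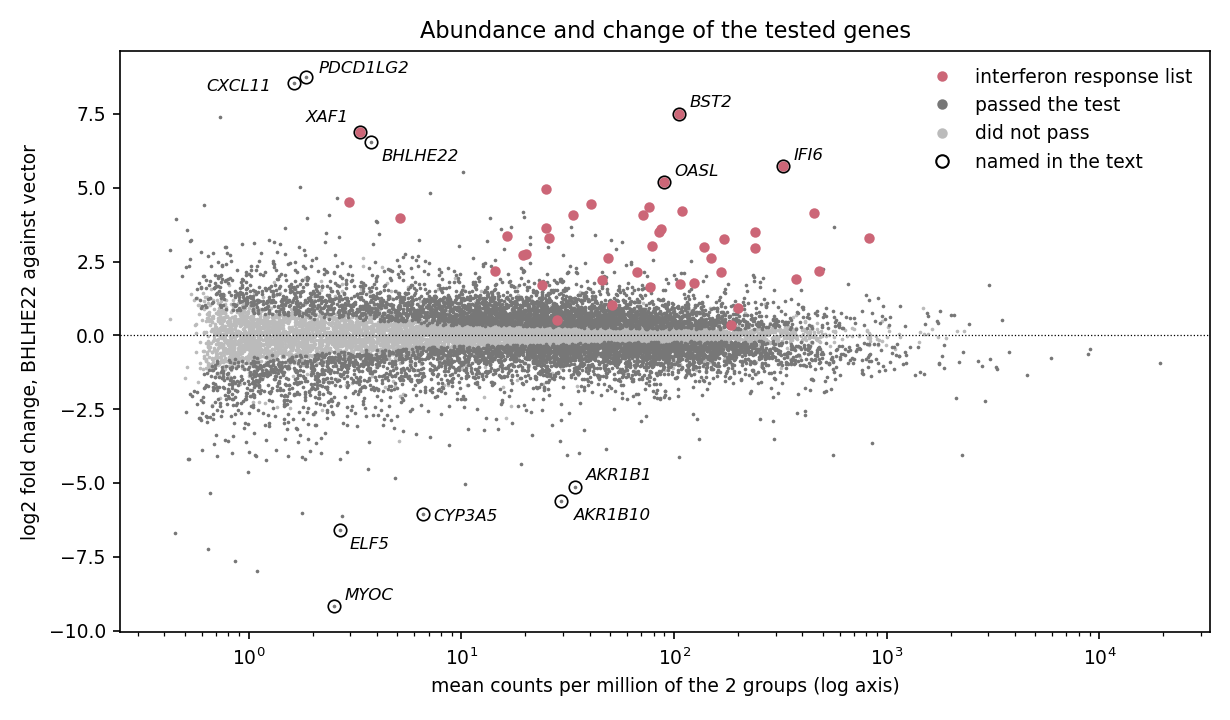
Mean CPM of the groups (log axis) against the log2 fold change for the 15945 tested genes. Circles mark some of the genes named in the text and filled red points the 42 members of the interferon response list. All 42 red points lie above 0, the highest being BST2 at 7.51; fitted values for PDCD1LG2, CXCL11 and MYOC, with no counts in 1 group, depend on the prior count.

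Every one of the 42 interferon-stimulated genes on the list rose in BHLHE22 cells, also when adjusted over the list alone. The median log2 fold change was 3.15, an 8.85-fold rise, with a range of 0.34 to 7.51. ISG15, a ubiquitin-like modifier, rose from 48.2 ± 1.0 to 857 ± 57 CPM, and the log2 fold changes of IFI44 and the RNA sensor DDX60 were 4.06 and 4.36. The list was called by camera (adjusted p = 3.72e-25), also with an estimated correlation (adjusted p = 0.0372). It was the only list of the 23 whose call held with an estimated correlation. Among markers of blood cells, PTPRC had 3 counts and TYROBP and HBB 0 over the BHLHE22 libraries. CD68 had 57.0 CPM in vector and 48.0 CPM in BHLHE22 cells (not called), and CORO1A rose from 2.04 ± 0.53 to 11.5 ± 1.1 CPM.

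Antigen presentation and checkpoint genes rose as well. Of 29 tested genes, 20 rose, 1 fell and 8 did not pass, and adjusted over the list alone the counts were 20 and 1. HLA-B and HLA-C, classical MHC class I genes, had log2 fold changes of 2.71 and 2.28. Those of NLRC5, the transactivator of MHC class I genes, and of the proteasome activator subunit PSME2 were 2.72 and 1.12. camera called the list (median 0.59, adjusted p = 1.10e-05). The call was lost with an estimated correlation (adjusted p = 0.239). TAP1 and PSMB8, chosen after their values were seen, were listed at 0 in all libraries, as were 73 of the 148 protein-coding genes of their region, so the HLA values here rest on a region with missing counts.

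Genes of secreted factors that attract or expand myeloid cells were mostly higher in BHLHE22 cells. Of 24 tested members, 16 rose, 1 fell and 7 did not pass; adjusted over the list alone, 16 rose and 2 fell. Without vector replicate 3, 15 rose and 3 fell, and 15 and 2 with the GC and length offset. CSF2 (ENSG00000164400, chromosome 5, 132073790 to 132076170), the gene of the growth factor GM-CSF, rose 2.89-fold, from 15.9 ± 5.1 to 46.0 ± 3.5 CPM (log2 fold change 1.53, SE 0.22, adjusted p = 0.00127, edgeR quasi-likelihood). The rise of CSF3, which encodes G-CSF, was 16.1-fold, from 2.30 ± 0.77 to 37.2 ± 11.1 CPM, and that of the cytokine gene IL6 12.7-fold, from 2.47 ± 0.37 to 31.6 ± 4.0 CPM. Neutrophil-attracting chemokines rose by log2 fold changes of 3.68 for CXCL5, 2.44 for CXCL3, 2.26 for CXCL8, 1.83 for CXCL2, 1.79 for CXCL6 and 1.75 for CXCL1. CXCL5, CXCL8 and CXCL1 reached 1052 ± 67, 828 ± 51 and 1007 ± 132 CPM. CCL20 rose by 3.43, CXCL16 by 1.27, IL1B by 0.63, LIF by 0.51 and MIF by 0.48. CCL28 and HMGB1 had log2 fold changes of 1.96 and 0.63 with adjusted p = 0.0375 for each (edgeR quasi-likelihood). Their calls ended without vector replicate 1 (adjusted p = 0.0664 and 0.0798), vector replicate 2 (0.0575 and 0.125), BHLHE22 replicate 2 (0.0951 and 0.0687) or BHLHE22 replicate 3 (0.105 and 0.0606), and without the low-count filter (0.131 and 0.0683). The call of HMGB1 also ended without vector replicate 3 (0.0720) and that of CCL28 with the GC and length offset (0.0502). S100A9, a calcium-binding protein of myeloid cells, fell from 12.2 ± 1.6 to 2.84 ± 0.39 CPM. camera called the list (median 0.95, adjusted p = 0.00142), and the call was lost with an estimated correlation (adjusted p = 0.239).

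The NF-kappaB target list shares 7 genes with the myeloid list, and its 4 leading members, IL6, CXCL8, CXCL1 and CCL20, are among them. Of 29 tested members, 14 rose, 4 fell and 11 did not pass; adjusted over the list alone, 14 rose and 4 fell. The count of falls was 2 without vector replicate 1 or 2 or BHLHE22 replicate 1 or 2, and 6 without vector replicate 3. Its median was 0.41 (camera adjusted p = 0.0235), with an adjusted p = 0.543 with an estimated correlation. Without vector replicate 3 the adjusted p was 0.0797.

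Cell cycle genes rose nearly as a whole. Of 42 S-phase and G2/M genes, 39 rose and 3 did not pass, and 40 rose when adjusted over the list alone. The median rise was 2.30-fold. CCNE2, a cyclin gene of the G1/S transition, had a log2 fold change of 3.23, and RRM2, a subunit gene of ribonucleotide reductase, 2.51. Those of DTL and the replication factor GINS2 were 2.39 and 2.36. The camera test called the list (adjusted p = 2.04e-13), and the call was lost with an estimated correlation (adjusted p = 0.543). Among bHLH factors, MYC rose from 11.5 ± 1.4 to 103 ± 5 CPM (log2 fold change 3.16, adjusted p = 6.04e-06, edgeR quasi-likelihood). MXD4, an antagonist of MYC, fell by 1.48, while HES4 and TCF4 rose by 1.49 and 0.96. The bHLH list as a whole was not called (4 rose and 8 fell of 23, also adjusted over the list alone; camera adjusted p = 0.698). Its median was -0.13 and its mean 0.01, camera pointed down and fry up, and with unscaled library sizes the median was 0.01.

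Protein arginine methyltransferase genes and PRMT5 partners were moderately higher. Of 12 tested genes, 10 rose, 1 fell and 1 did not pass, with 10 and 1 adjusted over the list alone. PRMT5 (ENSG00000100462, chromosome 14, 22920511 to 22929585) rose from 120 ± 2 to 181 ± 16 CPM (log2 fold change 0.59, SE 0.09, adjusted p = 0.00129, edgeR quasi-likelihood). WDR77, the gene of its partner protein MEP50, rose by 1.53 and PRMT3 by 1.13, while PRMT2 fell by 0.54. camera called the list (median 0.54, adjusted p = 0.0120), and the call was lost with an estimated correlation (adjusted p = 0.543). PRDM8 (ENSG00000152784, chromosome 4, 80183879 to 80204329), whose product is a known partner of BHLHE22 in neurons, fell from 130 ± 10 to 66.4 ± 18.1 CPM (log2 fold change -0.97, SE 0.19, adjusted p = 0.00563, edgeR quasi-likelihood).

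**Figure D3:**
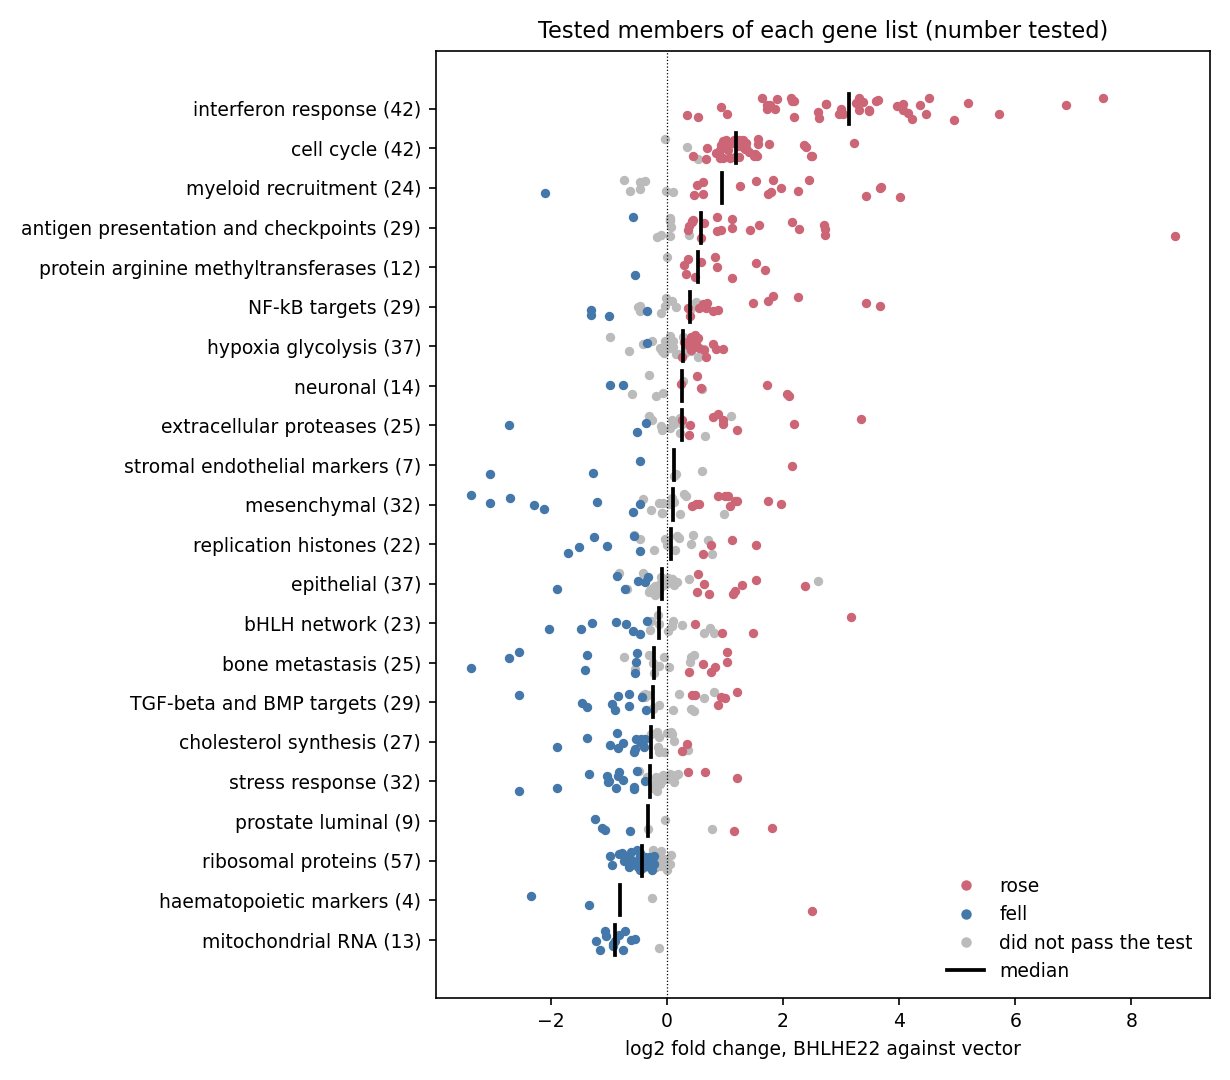
Log2 fold change of every tested member (points, coloured by whether it rose, fell or did not pass the test) of 22 gene lists, ordered by list median (black bars). Interferon response (median 3.15) and cell cycle stand highest and mitochondrial RNA (-0.89) lowest.

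Most ribosomal protein mRNAs were lower in BHLHE22 cells, with log2 fold changes of -0.97 to 0.08. Of 57 tested genes, 42 fell, 0 rose and 15 did not pass, and 44 fell adjusted over the list alone. The median was -0.42, with RPL13A at -0.77, RPS6 at -0.74 and RPL5 at -0.67. With unscaled library sizes the median was -0.28 and 28 fell. camera called the list (adjusted p = 1.44e-08), and the call was lost with an estimated correlation (adjusted p = 0.0767). Of 13 mRNAs of mitochondrial DNA, 12 fell and 1 did not pass, with the same counts adjusted over the list alone. Their median was -0.89 (camera adjusted p = 1.40e-05; adjusted p = 0.543 with an estimated correlation). MT-CO1, the most abundant transcript in every library, fell from 25342 ± 232 to 13292 ± 739 CPM. Log2 fold changes were -1.07 for MT-ND5, -1.05 for MT-CYB and -0.71 for MT-ND4L. Reads of mitochondrial genes made up 7.53% to 8.32% of the vector and 4.95% to 5.21% of the BHLHE22 libraries.

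Cholesterol synthesis and stress response genes were lower on balance. In the cholesterol list 13 of 27 genes fell and 2 rose, with the same counts adjusted over the list alone. Without BHLHE22 replicate 2, 7 fell. Without vector replicate 1 or 2 or BHLHE22 replicate 2 or 3, 0 rose, and 1 rose without BHLHE22 replicate 1, with DESeq2, without the low-count filter or with the GC and length offset. The regulators SREBF2 and SREBF1 had log2 fold changes of -0.97 and -0.85, and the enzyme gene MSMO1 -0.76. The camera test of this list gave an adjusted p = 0.0287 and a median of -0.27, with an adjusted p = 0.543 with an estimated correlation. It was 0.0646 without vector replicate 2 and 0.0541 without vector replicate 3. In the unfolded protein and integrated stress response list 14 of 32 genes fell and 3 rose (15 and 3 adjusted over the list alone), and 11 fell and 5 rose with unscaled library sizes. GDF15, a stress-induced cytokine gene, fell from 706 ± 288 to 121 ± 9 CPM, and SLC7A11 and ATF4 had log2 fold changes of -1.01 and -0.83. ATF3 rose by 1.22. The list had a median of -0.29 (camera adjusted p = 0.0239), with an adjusted p = 0.543 with an estimated correlation. Of 37 hypoxia and glycolysis genes, 15 rose and 1 fell, with the same counts adjusted over the list alone. The count of falls was 2 without vector replicate 3 or with DESeq2, limma-voom or the GC and length offset. It was 0 without BHLHE22 replicate 2 or 3 or with unscaled library sizes. The glycolytic genes GPI, PGAM1 and PGK1 rose by 0.97, 0.85 and 0.65, and the lactate transporter gene SLC16A3 by 0.79. The median of these genes was 0.28 (camera adjusted p = 0.0235), with an adjusted p = 0.543 with an estimated correlation. Without vector replicate 3 the adjusted p was 0.0747.

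Genes of adhesion, matrix and bone changed in both directions, and none of these lists was called by camera. FN1, the fibronectin gene, fell from 3447 ± 265 to 794 ± 73 CPM and S100A4 from 114 ± 19 to 23.2 ± 1.7 CPM, while the matrix genes THBS1 and TNC rose by 1.96 and 1.17. In the mesenchymal list 11 of 32 genes rose and 8 fell (11 and 9 adjusted over the list alone; adjusted p = 0.731), with a median of 0.11 and a mean of -0.10. Among 37 epithelial genes 9 rose and 6 fell (9 and 5 adjusted over the list alone; adjusted p = 0.993); KRT7, CLDN1 and EPCAM rose by 1.53, 1.29 and 1.17, and DSC2 fell by 0.71. Without vector replicate 1 or BHLHE22 replicate 2, or with unscaled library sizes, 3 fell. That list's median was -0.09, its mean 0.13 and, with unscaled library sizes, its median 0.06. In the bone metastasis list 6 of 25 genes rose and 8 fell, also adjusted over the list alone (adjusted p = 0.389), and 3 rose with the GC and length offset. SPARC, the gene of osteonectin, had a log2 fold change of -3.37, the BMP antagonist NOG -1.37, the protease CTSK -1.40 and the WNT antagonist DKK1 0.77. Of 25 extracellular protease genes and inhibitors 10 rose and 3 fell, also adjusted over the list alone. Only 1 fell without vector replicate 1 or BHLHE22 replicate 2 or 3, or with unscaled library sizes. ADAMTS6 rose by 3.34, CTSL by 0.97 and MMP17 by 0.80. The list had a median of 0.26 and an adjusted p of 0.0558, or 0.0137 without BHLHE22 replicate 3. Of 29 TGF-beta and BMP genes 6 rose and 10 fell, also adjusted over the list alone (median -0.24, adjusted p = 0.436). SMURF2 and SMAD6 fell by 0.95 and 0.89.

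The other lists were small or mixed, and camera called none of them. Among neuronal genes 14 of 42 could be tested, 6 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.594). Without vector replicate 2 or BHLHE22 replicate 2, 3 rose and 2 fell, and 4 rose when any other library was left out. MAP2 rose by 2.07 and the cadherin gene CDH11 fell by 0.75. TUBB2B rose by 1.72, its adjusted p was 0.0503 without vector replicate 2, and its log2 fold change was 1.11 without BHLHE22 replicate 3. Of 9 tested luminal prostate genes 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.443), while 1 rose and 5 fell without BHLHE22 replicate 2 or 3 or with DESeq2, and 3 rose and 4 fell without vector replicate 2. TMPRSS2, HOXB13 and SLC45A3 fell by 1.23, 1.07 and 0.63, and FKBP5 rose by 1.81. In the replication histone list 4 of 22 genes rose and 6 fell, also adjusted over the list alone (adjusted p = 0.886). With unscaled library sizes 9 rose and 4 fell, and 6 rose and 5 fell without BHLHE22 replicate 3 or with the GC and length offset. HIST1H2BD, HIST1H3E and HIST1H4H fell by 1.70, 1.51 and 1.02 and HIST1H2AE rose by 1.12; the median was 0.07, the mean -0.04 and camera pointed down.

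Most markers of other cell types were near or at 0 counts in both groups. Those at higher levels included the macrophage marker CD68 (57.0 ± 4.6 CPM in vector and 48.0 ± 3.8 CPM in BHLHE22 cells, log2 fold change -0.25, not called), COL1A1 (65.9 ± 6.1 and 47.6 ± 0.9 CPM), PECAM1 (55.7 ± 7.8 and 23.1 ± 3.6 CPM), PDGFRA (9.27 and 10.3 CPM, not called) and, named after their values were seen, KDR and ESAM (log2 fold changes 0.12 and 0.60, not called). Only 4 of 24 blood cell markers had enough counts to be tested. CORO1A rose by 2.50, CD14 and CD79A fell by 2.33 and 1.35 (3 fell adjusted over the list alone), and the adjusted p of the list was 0.443. Of 18 fibroblast and endothelial markers 7 were tested, 1 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.698), and 2 rose without BHLHE22 replicate 3. COL3A1, PECAM1 and COL1A1 fell by 3.04, 1.27 and 0.47, and LUM rose by 2.16, or 2.78 without vector replicate 1. The list's median was 0.12, while its mean was -0.25 and camera pointed down. The call of COL1A1 was lost with the GC and length offset (adjusted p = 0.0787). KLK3 had no counts, and the neuronal markers SYP, CHGA, SNAP25, STMN2 and ELAVL4 stayed under 1 CPM in every library.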

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

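The GC and length offset and the fit without mitochondrial genes were chosen after the result was seen; all other alternatives here were fixed before. BHLHE22 kept its call in every setting, with a log2 fold change of 6.48 to 6.62 when 1 library was left out, 6.12 with limma-voom and 6.70 with DESeq2. The count of called genes was 6303 to 7698 with 1 library left out, 7292 with the replicate number as a block, 7393 with DESeq2 and 7944 with limma-voom. It was 4962 at an adjusted p under 0.01, a stricter threshold by construction. The at least 2-fold count of 2602 was 2273 to 3013 with 1 library left out, and 3088 without the low-count filter. A test against a 1.2-fold change called 5655 genes; it differs in both the size of change and the form of the test. Under the block, 2555 genes changed at least 2-fold, and no list changed. Same-numbered libraries did not deviate together (correlations 0.0054, -0.027 and 0.010), and not every library correlated best with its own number. Of 113 named genes besides BHLHE22, 6 lost a call in at least 1 of 15 settings, 4 of them when a library was left out, and 0 reversed; CCL28 was the only one lost under the block (adjusted p = 0.102).

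No list reversed. With an estimated correlation the adjusted p was 0.239 for the myeloid and antigen presentation lists and 0.0767 for ribosomal proteins. It was 0.543 for NF-kappaB, cell cycle, hypoxia and glycolysis, cholesterol, stress, arginine methyltransferase and mitochondrial lists. With 1 library left out the adjusted p ranged from 0.0109 (without vector replicate 2) to 0.0797 (vector replicate 3) for NF-kappaB, from 0.00451 (vector replicate 2) to 0.0747 (vector replicate 3) for hypoxia and glycolysis, from 0.0153 (vector replicate 1) to 0.0646 (vector replicate 2) for cholesterol, and from 0.0137 (BHLHE22 replicate 3) to 0.116 (BHLHE22 replicate 1) for proteases. Proteases passed with DESeq2 (0.0245), limma-voom (0.0499), the GC and length offset (0.0263) and cameraPR on edgeR's statistics (0.0486). The list test under DESeq2 was cameraPR on DESeq2's statistics for 31773 genes, so it differs in the set test and the background too. fry, which asks whether a list changes rather than whether it changes more than other genes, called more lists. Its directional adjusted p was 0.0465 for neuronal, 0.00489 for bone metastasis and blood cell, 0.0104 for protease, 0.0310 for TGF-beta and BMP, 0.00564 for luminal and 0.00758 for stromal genes. Regardless of direction it was 3.03e-04 for neuronal and stromal, 2.35e-06 for bHLH, 3.09e-05 for mesenchymal, 8.55e-05 for bone metastasis, 5.82e-06 for protease, 1.08e-04 for luminal and 9.74e-04 for blood cell genes, and 8.42e-05 for the epithelial, TGF-beta and BMP and histone lists. The cause of the other differences was not tested. A pseudocount was not varied because counts were used, and the mitochondrial list has no value without its genes. At these depths the ratios for genes with few counts, such as XAF1, ELF5 and CCDC83, carry wide intervals.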

Other observations

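The genes in this and the next paragraph were chosen after the result was seen. So were the tests of blood cell transcripts, of shared SLC5A3 and MRPS6 reads, of tonicity and of other splits. The lists for interferon genes, NRF2 activity and growth arrest were also chosen after the result was seen. Several abundant transporter and aldo-keto reductase genes were far lower in the BHLHE22 libraries. SLC5A3, the myo-inositol transporter gene, fell from 4240 ± 1125 to 255 ± 15 CPM (log2 fold change -4.05), and SLC38A2, an amino acid transporter gene, from 4791 ± 767 to 1016 ± 181 CPM (-2.24). The taurine transporter gene SLC6A6 did not pass (197 ± 121 and 155 ± 13 CPM, log2 fold change -0.34, adjusted p = 0.654, edgeR quasi-likelihood). The urea transporter gene SLC14A1 fell by 3.84, AKR1C1 by 4.12 and AKR1C2 by 3.57. AKR1C1 and AKR1C2 are close paralogs, and SLC5A3 overlaps MRPS6 (-3.64), so reads of either pair cannot be separated here.

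The elongation factor genes EEF2 and EEF1A1 fell by 0.95 and 1.31. The pseudogenes EEF1A1P5 and EEF1A1P6 gave -1.34 and -1.31, and reads of these 3 EEF1A1 loci cannot be separated here. The chemokine gene CXCL10, not tested, had 1 count in vector and 36 in BHLHE22 libraries.

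The interferon-stimulated genes were higher in all BHLHE22 libraries. The highest of 5 blood cell transcripts reached 0.109% of the median interferon-stimulated gene's CPM there, which argues against blood cells as the source. The 5 held LAPTM5 in place of CD68, a marker fixed before the data were examined. CD68 had 48.0 CPM there, against 143 for the median interferon-stimulated gene, and 57.0 in vector cells. With CD68 among the 5, the test would have left blood cells open. PTPRC, LYZ, TYROBP and HBB, also fixed before, had 3, 7, 0 and 0 counts over the BHLHE22 libraries. With the GC and length offset the list's median stayed at 3.13, so that bias is not the cause of the rise. Interferon made by the cells stays open: counts of 8 interferon genes summed to 13 in the lowest BHLHE22 library and 62 in the highest vector library, mostly from IFNE, which fell by 1.76. IFNB1 (0 counts in vector and 11 in BHLHE22 libraries) and IFNL1 (1 and 10), singled out after their values were seen, went the other way from that sum; a response to the lentivirus or to BHLHE22 was not tested.

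For the fall of transporter and aldo-keto reductase genes, 5 genes away from SLC5A3 and MRPS6 had a median of -4.12. They were chosen because they fell, so the median is no test of the pattern. Their log2 fold changes ran from -2.24 (SLC38A2, SE 0.16) to -5.61 (AKR1B10, SE 0.24). Reads shared between SLC5A3 and MRPS6 cannot lower genes elsewhere, whatever the values there, so that sharing is no explanation for the 5 genes. This does not cover reads that AKR1C1 may share with AKR1C2. At that locus, SLC5A3 fell from 179188 counts over the vector libraries to 11031 over the BHLHE22 libraries, and MRPS6 from 66753 to 5402. Reads moved between the 2 genes cannot lower both, so these values argue against sharing as the cause of the fall there. Which of the 2 genes fell, or whether both did, stays open. For a higher tonicity of the vector cultures, 60% of 10 tested genes of a list written before lookup fell. HSPA4L rose by 1.48 and 3 did not pass, SLC6A6 among them. Of those that fell, AKR1B1 and S100A4 are also named by the rule, and AKR1B1 belongs to the pattern itself. The share is therefore not independent of the pattern. It lies between the bounds, which were set after the values were seen, so tonicity stays open. For lower NRF2 activity, the list had a median of -0.064 with a standard error of 0.213. Of its 22 tested members, 6 rose, 7 fell and 9 did not pass. The list was chosen after the main result was seen, so its bounds preceded its median at most, not the data. That median met the bound against this explanation by less than its standard error. Asking for a margin of 1 standard error was decided after the medians were seen and was applied to both bounds of this list and of the growth arrest list, so NRF2 activity also stays open.

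Cell cycle genes were higher and ribosomal protein mRNAs lower. The GC and length offset kept 99.8% of the distance between the medians, so that bias does not account for it. The ribosomal median was -0.28 under the scaling that brought it closest to 0, and both signs held, which met the bound set beforehand against scaling. That bound was wrong, since the scalings tried shift all genes by 0.15 at most, too little to reach 0. Scaling stays open for the sign of each list. It does not account for the distance between the medians, which was 1.62 with TMM, with DESeq2's size factors and with unscaled library sizes. A shift of all genes leaves that distance as it is by construction. Vector cultures nearer to growth arrest at harvest also stay open as an explanation. A list chosen after the main result was seen had a median of -0.51 with a standard error of 0.209. Of its 22 tested genes, 12 were lower and 2 higher. Its bound preceded its median at most, not the data. The median met that bound by less than its standard error (camera p = 0.00305, and p = 0.222 with an estimated correlation).

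Copy number differences between the cell pools were tested with medians of 148 windows of 100 neighbouring genes. Their SD was 0.112, above the highest of 1000 random gene orders (0.0936) but under the bound set for this explanation, which stays open. Random orders also separate neighbours that change together for other reasons, and the windows used fold changes without the GC and length offset. An SD above the random orders therefore does not by itself point to copy number. For both counts of changed genes, 1 of 10 splits of the libraries, the real one, reached the value. edgeR called 7876 genes for the real split and at most 0 for any other, where 107 to 326 genes had an unadjusted p under 0.05 against 8923. Every other split mixed vector and BHLHE22 libraries on each side. The difference between the groups then widened the spread within each side, so few or no calls were fixed in advance. The comparison with other splits therefore decides nothing. With 10 splits there are also too few for a share under 0.05.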
